A study of Arabidopsis thaliana with 6 samples.

How the data were processed

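RNA bound to tagged DCL4 was measured by RNA immunoprecipitation and sequencing in Arabidopsis thaliana, ecotype Columbia. The lines were DCL4-6:FHA and DCL4-8:FHA, tagged missense forms of DCL4 carried in the dcl4-2 mutant under the promoter of DCL4, and untagged wild type (WT). Each of the 3 lines was sampled in seedlings and in flowers, which gives 6 libraries and 1 library per group. Per the labels' protocols, the libraries were sequenced as single-end reads of 50 nt on an Illumina HiSeq instrument.

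The authors deposited read coverage at each position of 10 loci, as signal scaled to library size (RPM), with the libraries of a tissue side by side. The build was TAIR10, and HISAT2 2.0.5 and bedtools 2.25.0 were named, with no role given, per the submitters' processing notes. How reads with several matching places and the strands were handled is not given in the sources used here, and the values carry no strand. Some file labels call the seedling libraries seeds; the sample labels call them seedlings, and that name is used here.

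Within a library every deposited coverage value was a whole multiple of 1 step, to within 1.08e-08 of a read, and that step gave the library total. The totals were 17781670 reads for DCL4-6:FHA, 21771069 for DCL4-8:FHA and 1961876 for WT in seedlings. In flowers they were 15786416 for DCL4-6:FHA, 11255618 for DCL4-8:FHA and 15861072 for WT. The WT library of flowers was 8.08-fold deeper than that of seedlings, so background in seedlings is known less precisely. The sum of the coverage over a locus divided by 50 was taken as its number of reads. Because the values are coverage, no count model was fitted.

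Positions were read as counted from 1, as the files give them. Read this way, the coverage at 1177 pairs of matching bases in the arms of the IR71 inverted repeat differed by 0.143 to 0.212 times the difference that random assignment of reads would give in the 4 tagged libraries. Read as counted from 0, the values were 0.303 to 0.526, and r was 0.977 to 0.991 in place of 0.989 to 0.999. The position ranges of 8 of the 10 loci equal an annotated gene moved by 1 base, which taken alone would go with counting from 0; the choice rests on the IR71 arms. Both readings were computed, and the one with the smaller differences was kept after these were seen. Sequence and annotation came from the TAIR10.1 RefSeq assembly. Stretches of 50 nt were searched in the whole genome on both strands: 42.8% of those of IR71 and 98.0% of those of IR2039 occurred at a unique place, and 100% of those of each other locus did. For the intervals of IR71 and IR2039, the coverage at each base was divided by the mean number of places of the stretches that cover it.

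The level of a locus is its mean coverage over all positions. Ratios of levels carry an exact conditional 95% interval from the read numbers, and levels carry an exact Poisson 95% interval. Class medians carry an interval from 10000 Poisson resamples. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. With 1 library per group there was no test and no p-value, and no replicate check of any difference. Where a library had 0 reads at a locus, 3 reads were used as the floor and the fold is given as a lower bound, with reads of several places counted at a single place on both sides. Such a bound takes the numerator as measured and leaves out its own counting error. A locus is called above or below a comparator where the interval of the ratio excludes 1, and for a floor where the bound also exceeds 1.

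The interval procedure was tested on simulated reads of 50 nt over the loci, with 200 simulated loci per setting and the real library totals. For DCL4-8:FHA over DCL4-6:FHA in seedlings, 94.5% of intervals held a true ratio of 1 and 97.5% held a true ratio of 30. In flowers the shares were 94% and 96.5%. The simulated reads were independent and evenly placed, without duplicates or reads of several places. Such a test checks the calculation only, not whether real reads meet these conditions. Contrasts with WT were not simulated.

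The classes were fixed before the data were examined. The fold-back class holds IR71, IR2039 and miR822. The TAS class holds TAS1a, TAS1b, TAS1c, TAS2, TAS3a, TAS3b and TAS4. By the rule for named loci, all 10 are named with their level in all 6 libraries, along with the highest 50 nt bin of each tagged library and the arms and miRNA sites found from sequence. Arms were found by aligning each fold-back locus with itself in blastn 2.17.0, with at least 80% identity; miR822 reached 74.2%, so its sides of the alignment centre were used as an alternative chosen after the data were seen. miRNA sites were the best match to the annotated mature miR173, miR390 or miR828, and the cleavage point was set opposite bases 10 and 11 of the miRNA. Profiles were compared by Pearson's r over 50 nt bins where both libraries had at least 20 reads, a minimum set after the data were seen. The WT libraries had 0 to 4 reads per locus and gave no profile.

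Alternatives were the median and the maximum over positions, covered positions, the central 80% of a locus, pseudocounts of 0.1 and 1 RPM, a shift that sets the median ratio to 0, WT subtraction, other class members, other bin widths and other flanks. A split by strand was not run because the values carry no strand. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. RNA from before the immunoprecipitation was not analysed here, so levels are not corrected for the abundance of each transcript.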

Results

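DCL4 is the Dicer-like ribonuclease that cuts long double-stranded RNA into small interfering RNAs of 21 nt in Arabidopsis. The series asks how missense forms of DCL4 handle different classes of double-stranded substrate. RNA that precipitated with DCL4-6:FHA or DCL4-8:FHA was sequenced in seedlings and in flowers, with untagged WT plants as background. There were 6 libraries, 1 for each line and tissue, and no replicates. Library totals ran from 1961876 reads for WT in seedlings to 21771069 for DCL4-8:FHA in seedlings, an 11.1-fold range.

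The 10 loci fall into 2 classes. In the fold-back class the transcript pairs with itself. IR71 (chromosome 3, positions 1963599 to 1970598) is an inverted repeat that overlaps the annotated genes AT3G01835, AT3G00220, AT3G01845, AT3G06435 and AT3G06436. IR2039 (chromosome 3, 16158977 to 16161019) is an inverted repeat that overlaps AT3G44570 and AT3G44580. miR822 is made from the hairpin of MIR822 (AT5G03552, chromosome 5, 897019 to 897355), which lies within AT5G03553. In the TAS class a microRNA directs cleavage of a noncoding transcript, which is then copied into double-stranded RNA by RDR6. miR173 acts on TAS1a (AT2G27400, chromosome 2, 11721538 to 11722467), TAS1b (AT1G50055, chromosome 1, 18549203 to 18550041), TAS1c (AT2G39675, chromosome 2, 16537287 to 16538276) and TAS2 (AT2G39681, chromosome 2, 16539383 to 16540416). miR390 acts on TAS3a (AT3G17185, chromosome 3, 5861490 to 5862436) and TAS3b (AT5G49615, chromosome 5, 20134199 to 20134785). miR828 acts on TAS4 (AT3G25795, chromosome 3, 9417550 to 9418704). Ranges and positions are those the deposited values carry, on the TAIR10 build; the annotated bounds of TAS1a to TAS4 and MIR822 lie 1 base later.

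The comparison with WT asks which transcripts were above the background of untagged plants. WT differs from the tagged lines in its DCL4 as well as in the tag, since they carry missense forms in the dcl4-2 mutant. Ratios over WT may thus reflect transcript abundance as well as recovery through the tag, and these cannot be told apart here. In flowers, 9 of the 10 loci were above WT in DCL4-6:FHA and 9 in DCL4-8:FHA; TAS4 had 0 reads in all 6 libraries. In seedlings, 6 loci were above WT in DCL4-6:FHA and 8 in DCL4-8:FHA. The call of TAS1a with DCL4-6:FHA was lost when the maximum over positions was used, which left 5. All 3 fold-back loci were above WT in both lines and both tissues. With DCL4-8:FHA in flowers TAS2 was 3292-fold over WT (95% interval 1126 to 15969), from a WT level of 3 reads. Its maximum over positions was 1560-fold over that of WT. IR71 was 3033-fold over WT (839 to 25051), from a WT level of 3 reads, or 2 with each counted at a single place, and its log2 ratio fell from 11.57 to 9.55 at positions with unique stretches and to 8.52 with the maximum over positions. TAS3a was 8513-fold over a WT level of 1 read (1527 to 336307), or 5452-fold with the maximum over positions. With these ratios shifted so that their median is 0, a scaling that makes each locus relative to the others, the numbers above WT were 3 and 0 in flowers and 1 and 4 in seedlings.

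The WT library of flowers held 9 reads over the 10 loci, with 0 reads at 6 of them, and that of seedlings held 16 reads, with 0 at 4. Mean coverage in WT flowers was 0.00135 RPM at IR71, 0.00678 RPM at TAS1a, 0.00915 RPM at TAS2, 0.00333 RPM at TAS3a and 0 at IR2039, miR822, TAS1b, TAS1c, TAS3b and TAS4. In WT seedlings it was 0.0249 RPM at IR2039, 0.227 RPM at miR822, 0.0822 RPM at TAS1a, 0.122 RPM at TAS1b, 0.0257 RPM at TAS1c and 0.0739 RPM at TAS2. IR71, TAS3a, TAS3b and TAS4 had 0 reads there, where the floor of 3 reads is 0.0109 (for reads counted at a single place), 0.0807, 0.130 and 0.0662 RPM.

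The fold-back loci stood above this background with DCL4-6:FHA. In flowers IR71 reached 0.621 RPM, 460-fold over WT (95% interval 127 to 3801), with a log2 ratio of 8.84 that was 7.22 at positions with unique stretches. IR2039 reached 1.14 RPM, at least 247-fold higher, and miR822 reached 5.02 RPM, at least 179-fold higher. In seedlings IR71 reached 1.08 RPM, at least 66.9-fold higher with each read counted at a single place; at positions with unique stretches the bound was 3.24 on the log2 scale. With the maximum over positions IR71 was 89.4-fold over WT in flowers, and the bounds were 45.9-fold for IR2039 and 111-fold for miR822 in flowers and 4.67-fold for IR71 in seedlings. In seedlings IR2039 was at 0.444 RPM, 17.8-fold over WT (4.88 to 148), and miR822 at 4.58 RPM, 20.2-fold over WT (6.87 to 98.2). With the maximum over positions they were 5.96-fold and 15.5-fold over WT.

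Among the TAS loci with DCL4-6:FHA, TAS2 was above IR71 in both tissues and above IR2039 in seedlings, and the other TAS loci were below IR71. The IR71 level appears to count reads of several places at each place, with 1372 reads in flowers against 938 counted once. Its place above TAS3a in flowers, 0.621 against 0.511 RPM, may rest on this counting. In flowers TAS2 had 0.935 RPM, 102-fold over WT (34.7 to 499), and TAS3a 0.511 RPM, 153-fold over WT (27.1 to 6101). TAS1a had 0.105 RPM, 15.6-fold over WT (3.96 to 134). TAS1b at 0.113 RPM, TAS1c at 0.169 RPM and TAS3b at 0.140 RPM were at least 10.01-fold, 17.7-fold and 8.66-fold higher than WT. With the maximum over positions these bounds were 6.03-fold, 8.71-fold and 6.70-fold. By that measure TAS2 was 47.6-fold, TAS3a 99.5-fold and TAS1a 15.1-fold over WT in flowers. In seedlings TAS2 had 1.26 RPM, 17.1-fold over WT (5.80 to 83.0), and TAS3a 0.166 RPM, at least 2.06-fold higher (1.36-fold with the maximum over positions). TAS1a, at 0.257 RPM, was 3.12-fold over WT with an interval of 1.03 to 15.4. TAS1b at 0.0637 RPM and TAS1c at 0.139 RPM could not be told from WT at this depth, with ratios of 0.524 (0.174 to 2.12) and 5.40 (0.925 to 218). TAS3b had 2 reads in DCL4-6:FHA seedlings, 0.00958 RPM, and no ratio is given.

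Apart from TAS4, and from TAS3b in seedlings, the TAS loci were recovered at much higher levels with DCL4-8:FHA. In flowers coverage was 15.5 RPM at TAS1a, 8.89 RPM at TAS1b, 21.3 RPM at TAS1c, 30.1 RPM at TAS2, 28.3 RPM at TAS3a and 7.14 RPM at TAS3b. TAS3b was at least 443-fold higher than WT, or 320-fold with the maximum over positions. In seedlings coverage was 22.7 RPM at TAS1a, 2.87 RPM at TAS1b, 9.96 RPM at TAS1c, 32.1 RPM at TAS2 and 7.76 RPM at TAS3a. TAS1b was 23.6-fold over WT (9.21 to 86.9) and TAS2 was 435-fold over WT (149 to 2108). TAS3b had 10 reads, 0.0391 RPM, which lies below the floor of WT seedlings and could not be told from background. Among fold-back loci in flowers, IR71 was at 4.10 RPM, IR2039 at 3.87 RPM and miR822 at 2.38 RPM. In seedlings they were at 0.498, 1.26 and 6.36 RPM, which is at least 31.5-fold over WT for IR71 with each read counted at a single place (2.48 on the log2 scale at positions with unique stretches and 1.53 with the maximum), 50.6-fold for IR2039 (14.0 to 418) and 28.0-fold for miR822 (9.56 to 136). With the maximum over positions IR2039 was 15.2-fold and miR822 15.3-fold over WT in seedlings.

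**Figure D1:**
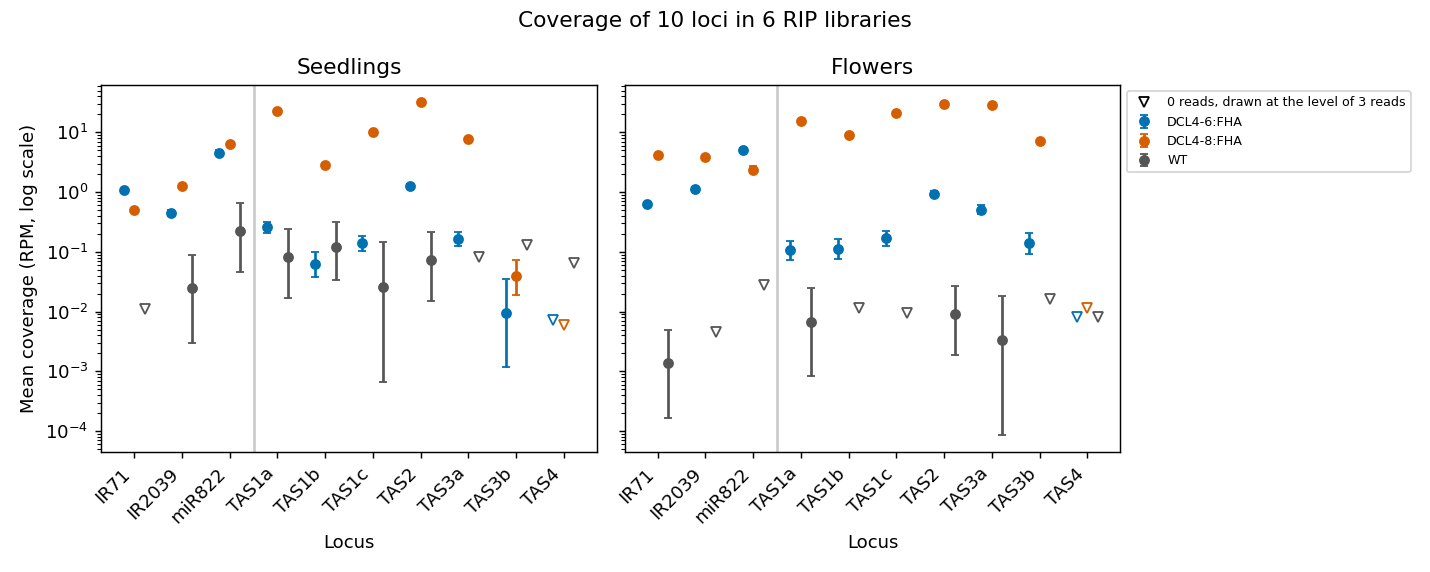
Mean coverage in RPM (log scale) at the 10 loci in seedlings (left) and flowers (right), 1 point per library, with bars for exact Poisson 95% intervals that cover counting error only; open triangles mark 0 reads and are drawn at the level of 3 reads. TAS loci of DCL4-8:FHA in flowers lie between 7.14 and 30.1 RPM except TAS4, and those of DCL4-6:FHA between 0.105 and 0.935 RPM.

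The comparison of the alleles asks whether they differ in the substrates they hold. At the TAS loci DCL4-8:FHA was far above DCL4-6:FHA, in 6 of 6 loci with reads in flowers and in 5 of 6 in seedlings. In flowers the ratio ran from 32.2-fold at TAS2 (95% interval 28.7 to 36.2) to 147-fold at TAS1a (103 to 216). It was 78.8-fold at TAS1b (54.97 to 117), 126-fold at TAS1c (95.9 to 168), 55.5-fold at TAS3a (47.2 to 65.6) and 51.1-fold at TAS3b (34.7 to 78.7). In seedlings it was 88.5-fold at TAS1a (71.5 to 111), 45.1-fold at TAS1b (28.7 to 75.2), 71.6-fold at TAS1c (54.1 to 97.0), 25.5-fold at TAS2 (23.2 to 28.0) and 46.7-fold at TAS3a (35.9 to 62.0). For TAS3b in seedlings it was 4.08 from 10 against 2 reads, with an interval of 0.870 to 38.3. When the median ratio of the loci is shifted to 0, TAS2 in flowers falls to the other side, with a log2 ratio of -0.67. With the maximum over positions the log2 ratio in flowers fell from 6.30 to 5.38 at TAS1b and from 6.97 to 6.29 at TAS1c. In seedlings TAS1b fell from 5.50 to 4.80. The DCL4-6:FHA levels of TAS1b and TAS1c in seedlings could not be told from WT, so their ratios there may have background as the denominator.

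At the fold-back loci the alleles differed less, and not in the same direction at each locus. IR2039 was higher in DCL4-8:FHA in both tissues, 3.38-fold in flowers (3.10 to 3.69) and 2.84-fold in seedlings (2.51 to 3.23). On the log2 scale these are 1.76 and 1.51, and with the median over positions they were 2.32 and 2.88. IR71 was 6.60-fold higher in DCL4-8:FHA in flowers (6.15 to 7.09) and 2.17-fold lower in seedlings (2.01 to 2.35), or 2.72 and -1.12 on the log2 scale, against 2.03 and -0.70 with the maximum over positions. miR822 was 2.10-fold lower in DCL4-8:FHA in flowers (1.78 to 2.51) and 1.39-fold higher in seedlings (1.25 to 1.55). The direction of miR822 in seedlings was lost with the maximum over positions, which gave a log2 ratio of -0.019 against 0.47. With the median ratio of the loci shifted to 0, each fold-back locus was lower in DCL4-8:FHA. That follows by construction, since most loci with a ratio are TAS loci and the median falls among them.

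The median log2 ratio of the TAS loci was 6.05 in flowers (95% interval 5.82 to 6.43) and 5.52 in seedlings (5.20 to 5.93). That of the fold-back loci was 1.76 in flowers (1.63 to 1.88) and 0.47 in seedlings (0.32 to 0.62). The fold-back medians rest on 3 loci and depend on the choices made. In seedlings the value was -0.32 without IR2039, -0.019 with the maximum over positions and 1.42 with the median over positions. In flowers it was 0.34 without IR71 and 0.61 with class sums. The difference between the classes was 4.29 in flowers (4.03 to 4.70) and 5.05 in seedlings (4.69 to 5.48), or 19.6-fold and 33.1-fold. It does not depend on a factor common to a library. Every TAS ratio in flowers exceeded every fold-back ratio, with a lowest TAS value of 5.01 and a highest fold-back value of 2.72. In seedlings the lowest TAS value, 2.03 for TAS3b, also exceeded the highest fold-back value, 1.51, but the interval of TAS3b reached below 0.

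**Figure D2:**
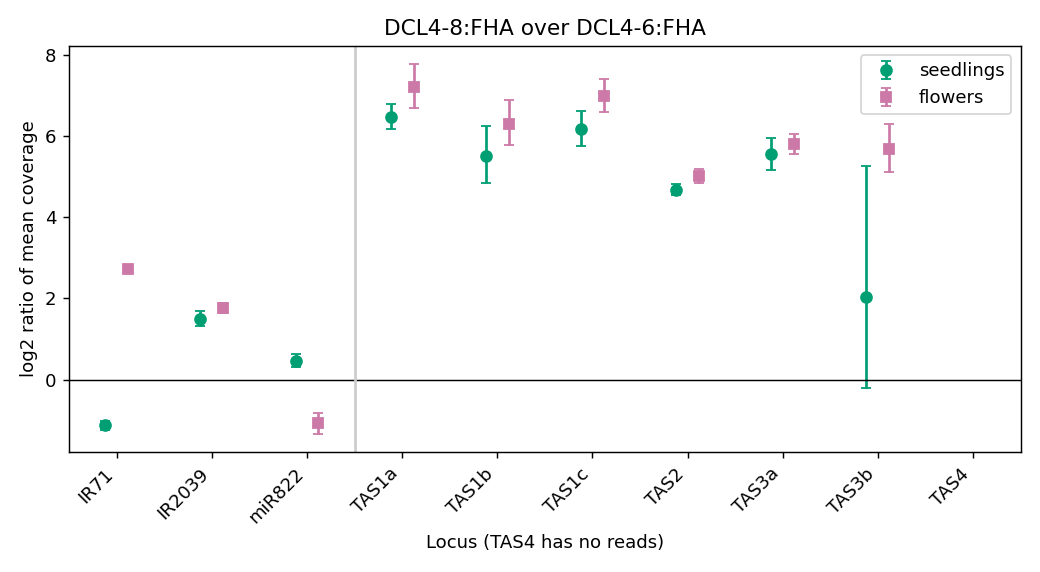
log2 ratio of mean coverage of DCL4-8:FHA over DCL4-6:FHA (vertical axis) by locus, in seedlings (circles) and flowers (squares), with bars for exact conditional 95% intervals that cover counting error only. TAS loci lie at 4.67 and above except TAS3b in seedlings at 2.03, and the fold-back loci lie between -1.12 and 2.72.

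Within a line, flowers and seedlings were compared to see which loci were recovered more in either tissue. Each comparison sets 1 library against another, and no shift for a library-wide factor was run here. Recovery of the immunoprecipitation, transcript abundance and tissue therefore cannot be told apart. By counting intervals alone, with DCL4-8:FHA 6 loci were higher in flowers and 3 were lower. TAS3b was 182-fold higher in flowers (95% interval 98.7 to 382), against 10 reads in seedlings that could not be told from background. IR71 was 8.23-fold higher (7.69 to 8.81), TAS3a 3.65-fold (3.50 to 3.81), TAS1b 3.09-fold (2.86 to 3.35), IR2039 3.07-fold (2.85 to 3.31) and TAS1c 2.14-fold (2.05 to 2.23). miR822 was 2.67-fold and TAS1a 1.47-fold lower in flowers, and TAS2 was 1.07-fold lower. With DCL4-6:FHA 3 loci were higher in flowers, 3 were lower and 3 could not be told apart. TAS3b was 14.6-fold higher (3.65 to 127, from 26 against 2 reads, the latter below the floor of WT), TAS3a 3.08-fold (2.251 to 4.26) and IR2039 2.58-fold (2.26 to 2.95). TAS1a was 2.43-fold, IR71 1.74-fold and TAS2 1.35-fold lower. Division by the WT level of the same tissue was possible only at TAS1a and TAS2, the loci with WT reads in both tissues. Both then turned to higher in flowers in both lines, from WT levels of 2 or 3 reads.

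Coverage along the TAS transcripts was set against the microRNA sites. The miR173 site lies at 11722081 to 11722102 in TAS1a, 18549660 to 18549681 in TAS1b, 16537890 to 16537911 in TAS1c and 16539991 to 16540012 in TAS2, with 19 or 20 of 22 bases paired. Between 99.8% and 100% of the coverage of these 4 loci lay 3′ of the cleavage point in all 4 tagged libraries. The miR390 sites lie at 5862099 to 5862119 and 5862343 to 5862363 in TAS3a and at 20134458 to 20134478 and 20134674 to 20134694 in TAS3b. In TAS3a 16 of 21 bases paired at each site, and in TAS3b 17 at the 5′ site and 14 at the 3′ site. The 3′ site of TAS3b is thus a weak match, with 12 paired bases in the next best stretch. At TAS3a and TAS3b, between 96.5% and 100% of the coverage lay between the sites, measured at the base opposite miRNA base 10 in each, and between 99.8% and 100% lay 5′ of the cleavage point of the 3′ site. The 5′ site of TAS3 is known to bind miR390 without being cleaved. The miR828 site of TAS4, at 9417809 to 9417830, had no coverage around it. The highest 50 nt bin was the same in all 4 tagged libraries at TAS1a (11721938 to 11721987) and at TAS3a (5862140 to 5862189). It held 31.9% to 43.1% of the coverage of TAS1a and 45.8% to 50.9% of that of TAS3a. At TAS3b the highest bin was 20134549 to 20134598 in DCL4-8:FHA seedlings, from 10 reads, and 20134499 to 20134548 in the other 3 tagged libraries. Of these, DCL4-6:FHA seedlings had 2 reads. The seedling reads of TAS3b, which also enter the shares given for the miR390 sites, were too few to tell from background. At TAS1b the highest bin was 18549503 to 18549552 in DCL4-8:FHA flowers and DCL4-6:FHA seedlings, 18549553 to 18549602 in DCL4-8:FHA seedlings and 18549453 to 18549502 in DCL4-6:FHA flowers. At TAS1c it was 16537687 to 16537736 in both lines in flowers, 16537787 to 16537836 in DCL4-8:FHA seedlings and 16537737 to 16537786 in DCL4-6:FHA seedlings. At TAS2 it was 16539833 to 16539882 in both lines in seedlings, 16539883 to 16539932 in DCL4-8:FHA flowers and 16539783 to 16539832 in DCL4-6:FHA flowers.

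Coverage of the hairpins was divided into arms and loop. The arms of IR71, at 1963723 to 1966967 and 1967205 to 1970450, are 98.9% identical and enclose a loop of 237 nt. They held between 98.0% and 99.7% of the coverage. They also make up most of the locus, with an alignment of 3249 nt, gaps included, for each arm within 7000 positions. Reads that match both arms cannot be assigned to either, so no difference in total coverage between the arms of IR71 is reported. Their matching bases were compared only to see how positions and reads were counted. The loop had 0.0938 times the coverage of the arms in DCL4-8:FHA flowers, 0.119 times in DCL4-6:FHA flowers, 0.206 times in DCL4-6:FHA seedlings and 0.537 times in DCL4-8:FHA seedlings. With reads of several places divided among them, these values were 0.143, 0.175, 0.307 and 0.783. In seedlings the loop itself was at 0.239 RPM with DCL4-6:FHA and 0.283 RPM with DCL4-8:FHA. The lower IR71 level of DCL4-8:FHA there thus lay on the arms. No interval was computed for the loop. The highest bin of IR71 lay near the loop in each tagged library, at 1966799 to 1966848 in both lines in flowers, 1967249 to 1967298 in DCL4-6:FHA seedlings and 1967199 to 1967248 in DCL4-8:FHA seedlings. IR2039 gave a single alignment with its own reverse complement, at 90.6% identity. It was split into arms at its centre, 16159953, so the absence of a loop is set by the split. Between 99.9% and 100% of the coverage lay on these arms. The alignment of 1965 nt, gaps included, takes up nearly all of the 2043 positions, so this share says little about IR2039. Its highest bin lay at 16159827 to 16159876 in DCL4-8:FHA in both tissues, at 16159877 to 16159926 in DCL4-6:FHA flowers and at 16160377 to 16160426 in DCL4-6:FHA seedlings. In 3 of the 4 tagged libraries the 50 nt around the centre of the miR822 hairpin, 897165 to 897214, had no coverage, and in DCL4-8:FHA seedlings they held 0.206% of it. The mature miR822 arms are annotated at 897067 to 897087 (3p) and 897287 to 897307 (5p). Its highest bin was 897019 to 897068 in both lines in flowers, 897069 to 897118 in DCL4-6:FHA seedlings and 897219 to 897268 in DCL4-8:FHA seedlings.

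Coverage profiles were compared between the alleles and between tissues. Across 50 nt bins, which are not independent replicates, r between DCL4-8:FHA and DCL4-6:FHA ran from 0.845 to 0.993 over 9 loci in flowers and from 0.836, at miR822, to 0.990 over 7 loci in seedlings. Between tissues it ran from 0.794 at IR71 to 0.993 with DCL4-8:FHA, over 8 loci, and from 0.898 to 0.992 with DCL4-6:FHA, over 7 loci.

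**Figure D3:**
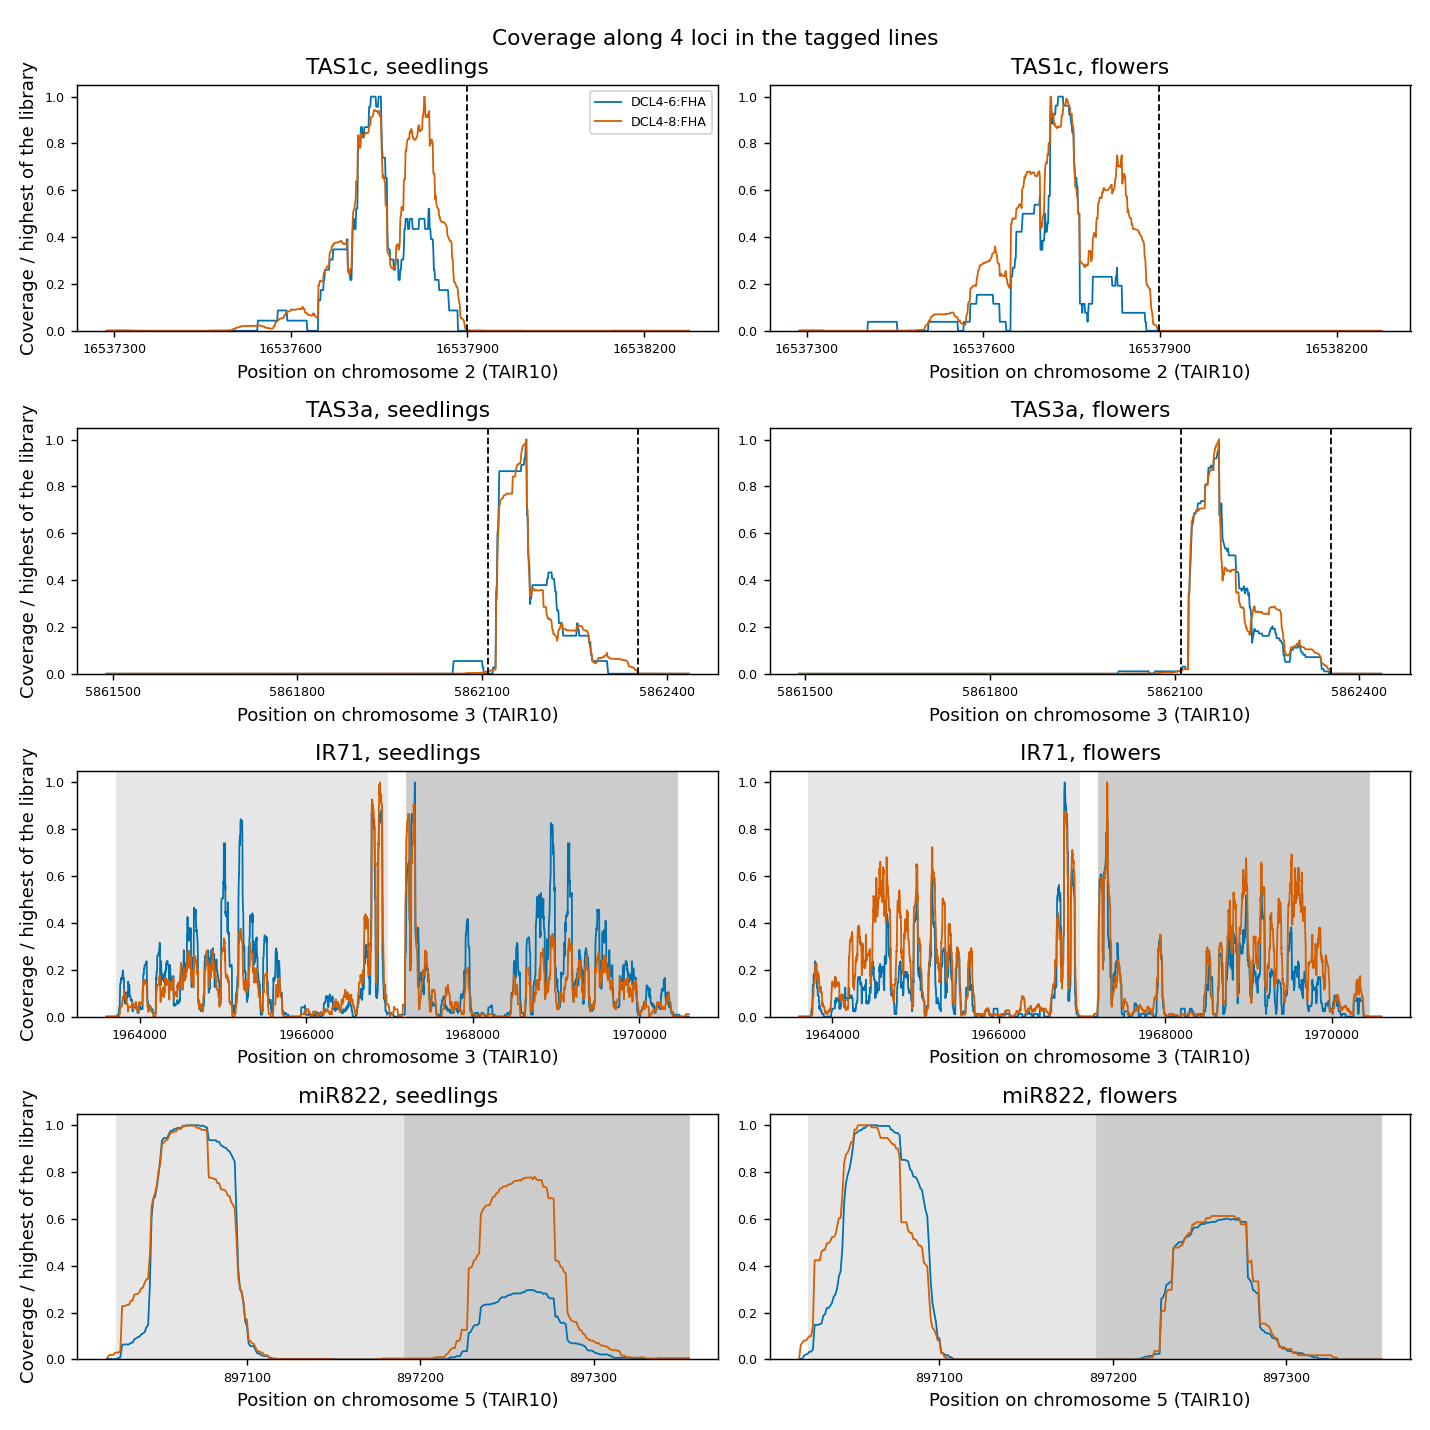
Coverage divided by the highest value of its library (vertical axis, no unit) against the position in the TAIR10 build, at TAS1c, TAS3a, IR71 and miR822 in seedlings (left) and flowers (right), 1 line per tagged library; dashed lines mark the base opposite miRNA base 10 at each site and grey areas the hairpin arms (for miR822 the sides of its centre). TAS1c is covered 3′ of the miR173 cleavage point, which is to its left on this minus-strand gene, and TAS3a between the miR390 sites.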

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

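The tests of a library-wide factor and of exchanged libraries in this part were chosen only after the result was seen; that at unique positions was added after the data were seen but before its own result was, and its reading by the sign of the interval was settled after.

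The ratio of DCL4-8:FHA over DCL4-6:FHA at IR71 took opposite directions in the tissues, with counting intervals that exclude 0 in each. The log2 ratio was 2.72 in flowers and -1.12 in seedlings, a difference of 3.84 that was not tested against replicates. A factor common to a whole library would move the fold-back loci alike, but the change at IR71 exceeded that at the nearest of IR2039 and miR822 by 3.22, counted from the interval bounds (TAS3b, with 2 and 10 reads in seedlings, changed by 3.65, interval 1.22 to 5.57). An exchange of the seedling libraries of the tagged lines would put the TAS loci lower in the library labelled DCL4-8:FHA, whereas their median log2 ratio there was 5.52. Reads counted at several places would give ratios of the same sign at the 1373 positions with unique stretches. Those gave 2.34 in flowers (95% interval 2.07 to 2.62) and -0.76 in seedlings (-1.04 to -0.48). The seedling interval excludes 0, but its upper end lies just above the bound of -0.5 set before the test. A tissue-dependent difference between the alleles is then a hypothesis, and transcript abundance, plant-to-plant variation and the immunoprecipitations of single samples remain open, since there are no replicates.

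miR822 took the opposite course, with a log2 ratio of -1.07 in flowers and 0.47 in seedlings, a difference of -1.55 that was likewise not tested. The seedling value was -0.019 with the maximum and 1.42 with the median over positions, so its direction rests on the summary used. In seedlings the side with the 3p arm was at 7.14 RPM with DCL4-6:FHA and 7.07 RPM with DCL4-8:FHA. The other side was at 2.18 and 5.86 RPM, so the lines differed mainly there.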

How the results depend on the processing

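The shift to a median of 0 for the allele ratio, unique positions, reads divided among their places, the 10-read minimum and the WT library of flowers as background were chosen after the data were seen. Leaving that shift aside, none of the 119 alternative values of each tagged line over WT changed the side of a called ratio, and 1 of 149 of DCL4-8:FHA over DCL4-6:FHA did: the maximum over positions gave -0.019 for miR822 in seedlings, which is also the fold-back median there. The median over positions gave no value over WT and none for the TAS class, because most medians are 0; at the fold-back loci it gave 2.88 for IR2039 and 1.42 for miR822, the class median, in seedlings, and 2.32 for IR2039, the class median, in flowers. With the maximum over positions 5 loci were above WT in DCL4-6:FHA seedlings instead of 6, TAS1a being lost. A pseudocount keeps the side of a ratio by construction. Covered positions gave the same ratios as the main analysis. At loci whose stretches were all unique, so did unique positions and reads divided among their places. The counts of 119 and 149 therefore include many values that could not turn, and they overstate how much was tested. The arms are the same alignments at 80% and 90% identity.

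The difference between the classes stayed above 0 under each alternative run. It was 4.26 in seedlings and 3.80 in flowers with 0.1 RPM added, and 2.69 and 2.77 with 1 RPM, which shrinks low levels. Leaving out each locus in turn gave 4.53 to 5.84 in seedlings and 3.81 to 5.70 in flowers, and class sums gave 5.21 in flowers. The fold-back median in seedlings ran from -0.32 without IR2039 to 0.99 without IR71; in flowers it was 0.34 without IR71, 0.82 without IR2039, 2.24 without miR822 and 0.61 with class sums. Each rests on 3 loci that differ.

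A shift to a median of 0 turns the loci below the median by construction. Over WT, DCL4-6:FHA gave -1.62 at TAS1a and -2.22 at TAS3a in seedlings, and -2.72 at TAS1a, -3.35 at TAS1b, -2.53 at TAS1c and -3.56 at TAS3b in flowers. DCL4-8:FHA gave -0.68 at IR71, -0.85 at miR822 and -1.10 at TAS1b in seedlings, and -1.41 at IR2039, -4.71 at miR822, -1.50 at TAS1b and -2.33 at TAS3b in flowers. The numbers above WT became 1 and 3 for DCL4-6:FHA and 4 and 0 for DCL4-8:FHA, in seedlings and flowers. DCL4-8:FHA over DCL4-6:FHA became -3.17 at IR2039 and -4.20 at miR822, the fold-back median, in seedlings, and -2.95 at IR71, -3.92 at IR2039, the fold-back median, and -0.67 at TAS2 in flowers.

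Divided by WT first, flowers over seedlings became 2.32 at TAS1a and 2.58 at TAS2 in DCL4-6:FHA, and 3.05 and 2.92 in DCL4-8:FHA; the cause was not tested. Against the deeper WT library of flowers, 8 loci were above background in DCL4-6:FHA seedlings, where WT of the same tissue gave 6. The WT libraries differ in tissue, in depth and in background, 8.16 RPM over the 10 loci together in seedlings and 0.504 RPM in flowers, so the change is not assigned to any of these.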

Other observations

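The tests of explanations in this part, the sides of miR822 and the rises of coverage were chosen only after the result was seen; the difference between the classes was planned.

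The sides of the miR822 hairpin were covered unequally, and in seedlings the lines differed in this. Coverage on the side with the 3p arm was 3.28 times that on the other side with DCL4-6:FHA (95% interval 2.68 to 4.02) and 1.21 times with DCL4-8:FHA (1.06 to 1.38), a ratio of 2.72 (2.15 to 3.47). In flowers the values were 1.61 (1.35 to 1.92) and 1.56 (1.15 to 2.14), a ratio of 1.03 (0.725 to 1.45). At TAS3a the steepest rise of coverage along the transcript fell at position 5862123 in all 4 tagged libraries, 231 nt before the cleavage point of the 3′ miR390 site, which is 11 times 21 nt. TAS3a was the only 1 of 6 TAS loci with such a distance in each library compared. In DCL4-8:FHA flowers the distance was 117 nt at TAS1a, 133 nt at TAS1b, 203 nt at TAS1c, 87 nt at TAS2 and 188 nt at TAS3b, none a multiple of 21 nt. The match also depends on reading positions as counted from 1. The position held between 23.4% and 26.1% of the rises of TAS3a; without it, between 0% and 2.68% lay in the 21 nt register, where an even spread gives 4.76%. The rise at TAS3a also lies just 3′ of the 5′ miR390 site, at 5862099 to 5862119, and these landmarks cannot be told apart here. These features were chosen after their values were seen.

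The TAS loci were higher in DCL4-8:FHA than in DCL4-6:FHA by far more than the fold-back loci. A factor common to a library, such as depth or recovery of the immunoprecipitation, predicts equal medians, which the class difference itself, with no further test, goes against: its lower bounds were 4.03 in flowers and 4.69 in seedlings on the log2 scale. A few amplified fragments would put the excess in a few bins. Of the 264 bins of 50 nt, 48 held at least 3 reads in DCL4-6:FHA, a choice made without the reads of DCL4-8:FHA. Of these, 100% were over 4-fold higher in DCL4-8:FHA, and the other bins were not judged. The excess was thus not confined to a few of the judged bins. These are the more covered bins, and reads of 50 nt reach into neighbouring bins, so amplified fragments within them are not excluded. Reads shared between TAS1 copies need repeated stretches, and 100% of the 50 nt stretches of each TAS locus were unique in the genome. An allele-dependent association with RDR6-made substrates and a difference in the abundance of TAS precursors between the lines both remain open: no value here separates them, which would need RNA from before the immunoprecipitation and replicates.

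Matching bases of the IR71 arms had nearly equal coverage. If each read were assigned at random to a single matching place, the depths would differ by chance, and the mean difference was at most 0.212 times that expectation in the 4 tagged libraries. With positions counted from 0 it was up to 0.526 times, above the limit of 0.5 set for the test, and the reading from 1 was itself kept because it gave the smaller differences, so the test is not independent of that choice. The likely reading is that a read with several matching places was counted at each, so the coverage of the IR71 arms may overstate the number of reads. No biological explanation was tested.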
